A study of Mus musculus with 28 samples.

How the data were processed

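Liver RNA of 15 C57BL/6 mice was compared on 28 two-colour arrays, per the labels. Total RNA was isolated with a spin-column kit, amplified, and coupled to the dyes Cy3 and Cy5, per the labels' protocols. The deposited table holds 1 value per spot and array, which is the authors' processed ratio of the dyes and was taken as a log2 ratio. Its log base is not stated and was taken as 2. The program limma is named in the submitters' processing notes, with no version or role. The authors' background correction, normalization and spot filters are not given in the sources used here. The array medians of the deposited log2 ratios ran from -0.23 to 0.35 and the array standard deviations from 0.29 to 1.26, so arrays were neither centred on the median nor brought to a common spread. Spot intensities were not used here, so signal over background is unknown for every gene.

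The direction of the ratios is not stated by the authors. It was read as the liver named second over the liver named first in a title, because the first array of each swap lists Cy3 for the first-named and Cy5 for the second-named liver and the design text describes dye swaps. The channel order on the second arrays, taken literally, would leave the dyes unexchanged. To check the reading used here, the mean dye effect of the other swaps was subtracted from each array. After that, 27 of 28 arrays correlated positively across genes with a fit made without their own pair (median r 0.351, lowest -0.0481, highest 0.615). Both the subtraction and the fit presume exchanged dyes. The fit also held mice of the tested pair through their other pairs, so it was not independent of the array. The r was near 0 for the second arrays of high-fat 10 and control 3 (0.0197), high-fat 6 and control 1 (-0.0481) and fasted 15 and control 2 (0.0304). The check hardly tests the sign of those arrays, and it bears only on the relative sign of arrays. The absolute sign stays likely, and turning it would exchange higher and lower in every comparison.

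Spots were named through the platform annotation paired with the table. Of 16416 spots 9758 carried 1 gene symbol, 0 carried several and 6658 had none. All 4799 symbols matched a RefSeq gene table of the mouse assembly GRCm38.p6 by Entrez number, which was used for names only, and no coordinates are given because the authors' build is not given in the sources used here. Spots of a gene were averaged: 4797 genes had 2 spots, Mecom had 4 and Gapdh had 160. Neighbouring spots of the same name correlated across the 14 mouse pairs, each the mean of a dye swap, with a median r of 0.512. Unnamed neighbours gave 0.423, and unrelated spots 0.0528. Unnamed spots were tested singly, which made 11457 features. There were 0 empty cells, and 0 columns of the table lacked a sample. Of the fixed panel of 32 liver metabolism genes, those without a named spot are not analysed here. Probes of close gene families, such as Cyp3a, Cyp4a, Saa, Hsd3b, Gstm, Acot and Lyz, can bind related transcripts, so values of those genes are uncertain as to the member.

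The 2 arrays of a swap were turned the same way and averaged, which cancels a gene's dye bias, and counted as 1 replicate. Before turning, the arrays of a swap should correlate negatively; their r ran from -0.525 to 0.301 and was positive in 9 of 14 swaps. With the mean dye effect of the other swaps removed it was still positive in 4, up to 0.417 for fasted 14 and high-fat 7. A dye bias of the same size in all swaps therefore does not account for all of it. Dye bias that differs between swaps was not removed, and the cause was not tested. The dye effect itself passed the limma threshold at 1241 features with more signal in Cy5 and 1125 with less, 20.7% of 11457. With each array centred on its median these were 608 and 1429.

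The 14 pairs were fitted together by generalised least squares with 3 groups. Pairs that share a mouse are correlated with a known sign, and the share of variance between mice was estimated at 18.1%, the trimmed mean over features. The median over features was 0.04 and the pooled estimate 0.08 on the same scale, and in simulations with a share of 0.181 the trimmed mean returned 0.261, above the true share. The fit was moderated with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes; 12 residual and 4.51 prior degrees of freedom), and p-values were adjusted by Benjamini-Hochberg over all 11457 features, with a threshold of 0.05. A gene needed both arrays of at least 10 pairs, and every feature met this. The mice are separate animals, per the labels. Of the 15 mice, 12 are linked by shared hybridisations, and control 1, high-fat 6 and fasted 12 form a chain of their own. Direct and indirect ratios of fasted over high-fat livers correlated across 11457 features with r = 0.686. Both ratios use mostly the same fasted and high-fat mice, so chance values of a mouse enter both and can raise r. The replicate numbers in the titles name single mice and do not pair mice across groups.

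Lists of 43 pathways, complexes and cell types were fixed before the data were examined, as were the groups, the tests and most alternatives. The 41 lists with at least 5 measured genes were tested against all other named genes with camera, two-sided, at a preset correlation of 0.01, adjusted over the lists within a comparison. Camera with a correlation estimated from the data and camera on ranks were alternatives. None of the list calls held with an estimated correlation, and 10, 8 and 13 of them held on ranks in fasted against control, high-fat against control and fasted against high-fat. Named genes were the 10 largest increases and 10 largest decreases past the threshold with the same sign in every direct pair, up to 4 members of each list with the smallest p past the threshold, and the fixed panel. The text names part of these, chosen by list and by size, and says where a gene falls outside the rule. The 10 genes called in both fasted and high-fat livers are named as the members of that overlap.

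Alternatives covered centring and scaling of arrays, the mouse effect, direct pairs only, 1 array of each swap only, a robust prior, single spots, a filter on spread, stricter thresholds, leaving out each mouse, and leaving out the separate chain. Leaving out the pair with the widest array, weighting pairs by quality, adjusting over named genes only and averaging adjacent unnamed spots were added after seeing the data.

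The procedure was tested on simulated data with the same arrangement of mice, 200 changed genes among 11457 features and 5 runs. For fasted against control it recovered 67.6% of genes changed by a log2 of 0.5, 97.9% of those changed by 1 and 100% of those changed by 2, and 4.40% of its calls were false. For high-fat against control these were 71.1%, 97.9%, 100% and 6.22%. Taking the pairs as independent gave 7.32% and 11.1% false calls. These rates are for a simulated share of variance between mice of 0.181. At a share of 0.5 the fit gave 6.21% and 4.48% false calls, and independent pairs gave 15.6% and 15.4%. The comparison of fasted with high-fat livers was not simulated. Unequal spread between arrays was not among the simulated settings, whereas the real array standard deviations ran from 0.29 to 1.26. The rates of recovery and of false calls therefore hold for the simulated data and may not carry over to these arrays.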

Results

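RNA from the livers of 15 C57BL/6 mice, an inbred laboratory strain, was compared on 28 two-colour microarrays. The mice were 12 to 16 weeks old and fell into 3 groups of 5. Control mice ate chow for 2 weeks, fasted mice ate chow and then went without food for 16 hours, and high-fat mice ate a fat-rich diet for 2 weeks. Their sex is not given in the sources used here. Each array carried RNA of a pair of mice, 1 in each dye, and each pair was put on 2 arrays with the dyes exchanged. Such a dye swap counted as 1 measurement. There were 14 pairs: 4 of fasted with control mice, 5 of high-fat with control mice and 5 of fasted with high-fat mice. The array held 16416 spots, of which 9758 carried the names of 4799 genes, and the other 6658 spots have no gene name here. The deposited values are ratios without spot brightness, so the signal over background is unknown, and the number of pairs limits the precision.

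Ratios were read as the liver named second over the liver named first in each array's title, on a log2 scale. Neither the direction nor the log base is stated in the sources used here. The direction is likely rather than certain: it rests on the order of the titles and on the dyes given for the first array of each swap. Turning it would exchange higher and lower in every comparison that follows. Values are log2 ratios ± the standard error of a limma fit over all 14 pairs, with p adjusted by the Benjamini-Hochberg method, and values over directly hybridised pairs are means ± SD.

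The first comparison asked how liver transcript levels differed after a 16 hour fast. In fasted livers 199 of the 4799 named genes were higher and 266 were lower than in controls. Apoa4, which encodes an apolipoprotein of triglyceride-rich lipoproteins, had the largest increase, 4.62 ± 0.18 or 24.5-fold (adjusted p = 1.16e-10). Over the 4 directly hybridised pairs it was 4.99 ± 0.30 (SD, n = 4). Cyp4a14, a fatty acid hydroxylase and known target of the nuclear receptor PPARalpha, rose by 3.38 ± 0.24 (adjusted p = 1.04e-07). Pkm, the muscle form of pyruvate kinase, rose by 3.40 ± 0.31 (adjusted p = 1.82e-06) and Ldhb, a lactate dehydrogenase subunit, by 2.13 ± 0.13 (adjusted p = 1.31e-08). Among the decreases, Car3, a carbonic anhydrase abundant in liver, muscle and fat, changed by -2.75 ± 0.25 (adjusted p = 1.73e-06) and Camp, the antimicrobial peptide cathelicidin, by -2.14 ± 0.20 (adjusted p = 3.55e-06). Each of these genes moved the same way in 4 of 4 direct pairs. Camp is also a neutrophil marker and Car3 an adipocyte marker; 1 of 8 neutrophil and 1 of 5 adipocyte markers fell, and neither list passed camera (medians -0.10 and -0.02, camera adjusted p = 0.166 and 0.246).

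**Figure D1:**
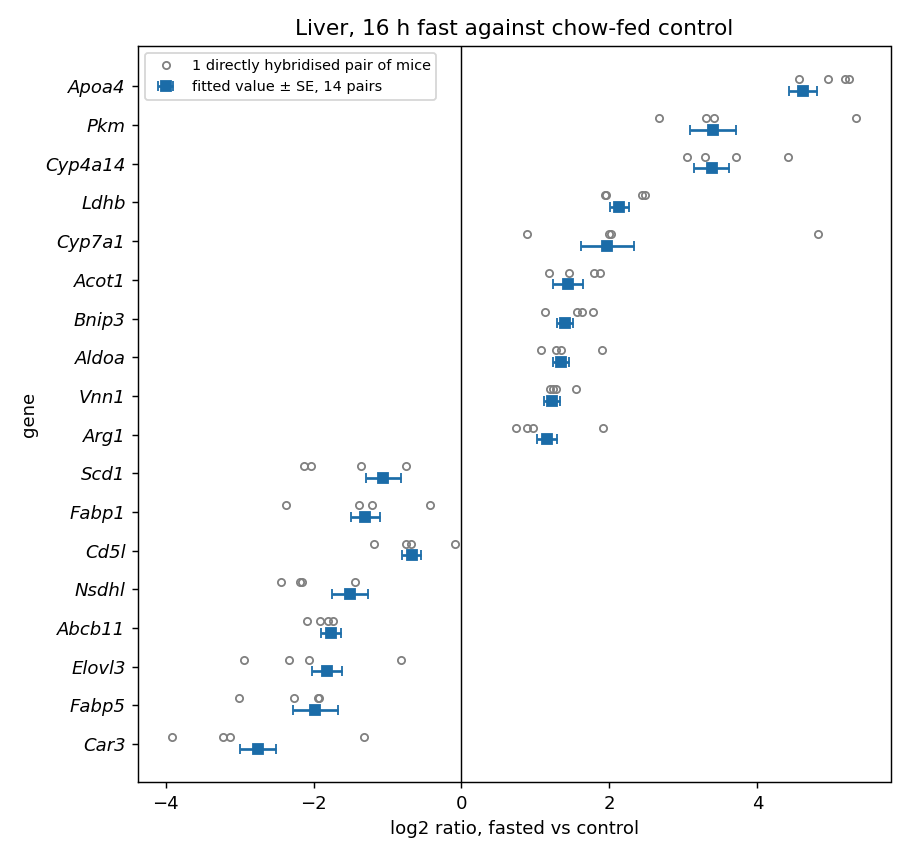
Log2 ratio of fasted over control liver (horizontal axis) for genes named in the text (vertical axis). Open circles are the directly hybridised pairs of mice (n = 4), squares are the fitted values over 14 pairs with their standard errors, and Apoa4 lies farthest to the right, at 4.62.

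Genes of fatty acid oxidation were higher after the fast. Of 10 measured genes of peroxisomal and microsomal oxidation 7 rose, 0 fell and 3 did not pass, with 8 higher when adjusted over the list alone. The median was 0.52 (camera adjusted p = 3.56e-09; adjusted p = 0.192 with an estimated correlation). Besides Cyp4a14, the list's largest changes by p were in the acyl-CoA synthetase Slc27a2 (0.59 ± 0.07), Ech1 (0.59 ± 0.08) and Hsd17b4 (0.56 ± 0.09), enzymes of fatty acid activation and breakdown. Of 7 measured genes of mitochondrial oxidation 5 rose and 0 fell, the same numbers as adjusted over the list alone, with a median of 0.37 (camera adjusted p = 0.000262; adjusted p = 0.213 with an estimated correlation). They included the dehydrogenases Acadm (0.45 ± 0.08) and Acadl (0.48 ± 0.09) and the mitochondrial acylcarnitine carrier Slc25a20 (0.46 ± 0.09). Of 15 other genes known to be regulated by PPARalpha 5 rose, 1 fell and 9 did not pass (9 and 1 when adjusted over the list alone; camera adjusted p = 0.000202; adjusted p = 0.213 with an estimated correlation). The pantetheinase Vnn1 rose by 1.22 ± 0.10, the acyl-CoA thioesterase Acot1 by 1.44 ± 0.21 and Fabp2, an intestinal fatty acid-binding protein, by 0.81 ± 0.12. Fabp1, the liver fatty acid-binding protein, went the other way at -1.30 ± 0.19 (adjusted p = 0.000322). Pdk4 (0.15, adjusted p = 0.5), Angptl4 (-0.10, adjusted p = 0.769) and Fgf21 (0.47 ± 0.15, adjusted p = 0.0729), classical fasting genes of the same list, did not pass. With the first array of each swap alone, which leaves the dye bias in, Angptl4 was at 0.46 (adjusted p = 0.0309).

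Of 10 measured genes of gluconeogenesis 3 rose and 0 fell, with 4 higher when adjusted over the list alone (median 0.35, camera adjusted p = 0.00494; adjusted p = 0.263 with an estimated correlation). Pcx, pyruvate carboxylase, rose by 0.63 ± 0.07 (adjusted p = 8.04e-06) and Slc37a4, which carries glucose 6-phosphate into the endoplasmic reticulum, by 1.27 ± 0.14 (adjusted p = 2.28e-05). The rate-setting enzymes Pck1 (0.44 ± 0.16, adjusted p = 0.121) and G6pc (-0.02 ± 0.17, adjusted p = 0.966) did not pass, nor did the coactivator Ppargc1a (0.25 ± 0.11, adjusted p = 0.211). Of 11 glycolysis genes 3 rose and 1 fell, the same as adjusted over the list alone (median 0.07, camera adjusted p = 0.0405; adjusted p = 0.263 with an estimated correlation). The members that rose were Pkm, the aldolase Aldoa (1.35 ± 0.11, adjusted p = 5.52e-07) and the lactate dehydrogenase subunit Ldha (0.57 ± 0.08, adjusted p = 0.000243), enzymes that also serve glycolysis outside the liver. Khk, the ketohexokinase of fructose metabolism, changed by -0.59 ± 0.09 (adjusted p = 0.00039).

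Lipid synthesis genes were lower. Of 10 measured genes of fatty acid and triglyceride synthesis 5 fell and 0 rose, as when adjusted over the list alone (median -0.19, camera adjusted p = 0.00494; adjusted p = 0.263 with an estimated correlation). The elongase Elovl3 changed by -1.82 ± 0.20 (adjusted p = 1.43e-05), the acetyl-CoA synthetase Acss2 by -1.08 ± 0.13 (adjusted p = 5.38e-05), Mlxipl, the carbohydrate-sensing transcription factor ChREBP, by -0.89 ± 0.10 (adjusted p = 2.06e-05) and the desaturase Scd1 by -1.06 ± 0.23 (adjusted p = 0.00801). The Scd1 call was lost without control mouse 4 (adjusted p = 0.0604) and without fasted mouse 11 (adjusted p = 0.0846). Of 7 cholesterol synthesis genes 5 fell and 0 rose, with 6 lower when adjusted over the list alone (median -0.53, camera adjusted p = 5.91e-05; adjusted p = 0.213 with an estimated correlation). Nsdhl (-1.51 ± 0.25, adjusted p = 0.000754) and Ebp (-0.71 ± 0.08, adjusted p = 2.32e-05), enzymes of the late pathway, were among them.

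Genes of bile acid synthesis and transport moved both ways: 4 of 12 rose and 3 fell, against 5 and 6 when adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.831). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 1.97 ± 0.35 (adjusted p = 0.00162), Cyp8b1, which directs synthesis towards cholic acid, by 1.08 ± 0.15 (adjusted p = 0.000152) and the bile acid receptor gene Nr1h4 by 0.55 ± 0.09 (adjusted p = 0.0011). Abcb11, the bile salt export pump, changed by -1.76 ± 0.14 (adjusted p = 3.89e-07). In amino acid catabolism and the urea cycle 5 of 13 genes rose and 2 fell, against 5 and 3 when adjusted over the list alone (camera adjusted p = 0.408). Arg1 (1.15 ± 0.14), the arginase that releases urea, and Aass (1.25 ± 0.16), of lysine breakdown, were higher, whereas the urea cycle enzyme Otc (-0.85 ± 0.13) and the glutamate dehydrogenase Glud1 (-0.72 ± 0.11) were lower. Bhmt, which remethylates homocysteine, rose by 1.52 ± 0.19 (adjusted p = 6.44e-05).

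Genes for secreted proteins and for resident immune cells were lower. Of 11 plasma protein genes 6 fell and 0 rose, with 7 lower when adjusted over the list alone (median -0.37, camera adjusted p = 0.000202; adjusted p = 0.263 with an estimated correlation). Serpina6, which binds corticosteroids, changed by -1.22 ± 0.18 and the thyroid hormone carrier Ttr by -0.74 ± 0.13. Ttr was at 0.64 in the first arrays of the swaps alone, which leave the dye bias in. Of 12 markers of Kupffer cells, the liver's resident macrophages, 7 fell and 0 rose, against 7 lower and 1 higher when adjusted over the list alone (median -0.42, camera adjusted p = 0.000516; adjusted p = 0.263 with an estimated correlation). Cd5l (-0.68 ± 0.13), C1qc (-0.57 ± 0.11) and Clec4f (-0.49 ± 0.11) were among them, and the Clec4f call was lost without fasted mouse 11 (adjusted p = 0.0527). Of 13 interferon response and antigen presentation genes, many of which macrophages also express, 6 fell and 0 rose, as when adjusted over the list alone (median -0.29, camera adjusted p = 0.000569; adjusted p = 0.304 with an estimated correlation). The immunoproteasome subunit Psmb10 changed by -0.53 ± 0.11, and its call was lost without control mouse 4 (adjusted p = 0.061) and without fasted mouse 11 (adjusted p = 0.0642). Medians of the other cell type markers were -0.06 for endothelial cells, -0.13 for stellate cells and fibroblasts, -0.09 for cholangiocytes, -0.01 for lymphocytes and -0.11 for erythroid cells, and none of these lists passed camera. Among them 2 of 5 erythroid markers fell and 0 rose, Hba-a1 (-0.65 ± 0.17) and Fech (-0.42 ± 0.10), as when adjusted over the list alone, and 2 of 10 endothelial markers, Kdr (-0.30 ± 0.09) and Tek (-0.33 ± 0.10), fell and 0 rose, with 3 lower when adjusted over the list alone. The stellate cell marker Dcn rose (0.29 ± 0.08). These calls were lost in 4, 5, 11, 10 and 13 of 15 omissions of a mouse.

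A further 4 lists passed camera. Of 10 growth hormone responsive and sex-biased genes 3 fell and 0 rose, with 4 lower when adjusted over the list alone (camera adjusted p = 0.000569; adjusted p = 0.213 with an estimated correlation), among them Elovl3 and the complement gene C6 (-0.66 ± 0.12). Of 16 proteasome genes 4 rose and 0 fell, with 6 higher when adjusted over the list alone (camera adjusted p = 0.00494; adjusted p = 0.343 with an estimated correlation), including the ubiquitin receptor Psmd4 (0.62 ± 0.09). Of 12 genes of translation and ribosome biogenesis 3 rose and 0 fell, the same as adjusted over the list alone (camera adjusted p = 0.0405; adjusted p = 0.263 with an estimated correlation), including the nucleolar protein Npm1 (0.46 ± 0.08). Of 6 unfolded protein response genes 1 fell and 0 rose, as when adjusted over the list alone (camera adjusted p = 0.0325; adjusted p = 0.343 with an estimated correlation). Among single genes outside these lists, the fatty acid-binding protein Fabp5 changed by -1.98 ± 0.30 (adjusted p = 0.00041) and the steroid dehydrogenase Hsd3b1 by -1.91 ± 0.26 (adjusted p = 0.000152).

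At unadjusted p below 0.05, 1020 named genes differed between fasted and control livers, and 185 unnamed spots were higher and 259 lower after adjustment. The split was 221 higher and 169 lower when arrays were scaled to the same spread. The total of 465 became 57 with the 4 direct pairs alone, 1559 with the first array of each swap alone and 79 with the share of variance between mice set to 0.9, and it was 266 without control mouse 4, 294 without control mouse 5, 245 without fasted mouse 11 and 291 without fasted mouse 13.

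The second comparison asked how liver transcript levels differed after 2 weeks of fat-rich feeding. In high-fat livers 3 of the 4799 named genes were higher and 13 were lower than in controls. Apoa4 rose by 1.88 ± 0.18, or 3.68-fold (adjusted p = 1.33e-05), and Fabp2 by 1.38 ± 0.11, or 2.6-fold (adjusted p = 1.92e-06), each in 5 of 5 direct pairs. Over those pairs the means were 1.60 ± 0.30 for Apoa4 and 1.44 ± 0.42 for Fabp2 (SD, n = 5). Cyp3a41a, a cytochrome P450 of female-biased expression, changed most, by -3.15 ± 0.19, with a mean of -3.12 ± 0.66 (SD, n = 5) over the direct pairs (adjusted p = 5.45e-08). The Cyp3a genes are similar in sequence, so its probe can also read close relatives. Hs6st3, a heparan sulfate sulfotransferase (-1.26 ± 0.18, adjusted p = 0.0026), and the carbonic anhydrase Car14 (-0.71 ± 0.10, adjusted p = 0.00196) were also lower in 5 of 5 pairs.

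**Figure D2:**
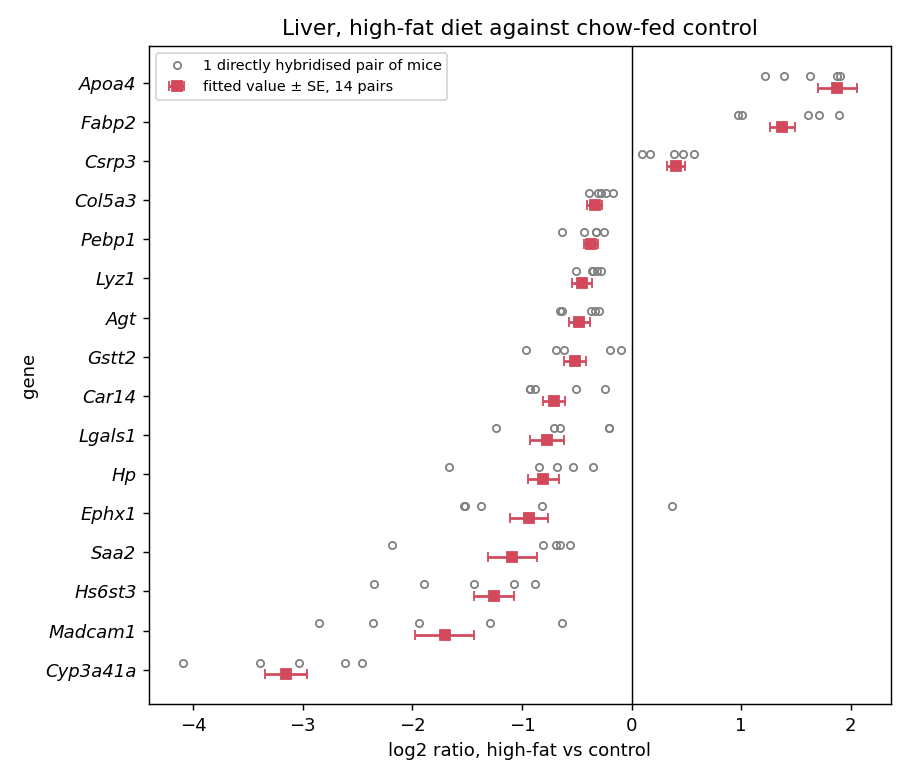
Log2 ratio of high-fat over control liver (horizontal axis) for the 16 named genes past the threshold (vertical axis). Open circles are the directly hybridised pairs of mice (n = 5) and squares are the fitted values over 14 pairs with their standard errors, from -3.15 for Cyp3a41a to 1.88 for Apoa4.

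These 5 genes passed in every omission of a single mouse, and the other 11 did not. The adhesion molecule Madcam1 (-1.71 ± 0.27, adjusted p = 0.00581) lost its call without control mouse 2 (adjusted p = 0.0516) and without high-fat mouse 9 (adjusted p = 0.125). Haptoglobin, Hp, an acute phase protein (-0.81 ± 0.14, adjusted p = 0.0199), lost it in 5 of 15 omissions, with adjusted p up to 0.154. The acute phase gene Saa2 (-1.09 ± 0.22, adjusted p = 0.0449) lost it in 12, with adjusted p up to 0.316. The detoxification enzymes Ephx1 (-0.94 ± 0.17, adjusted p = 0.0235, lower in 4 of 5 pairs) and Gstt2 (-0.51 ± 0.10, adjusted p = 0.0404) each lost it in 11, with adjusted p up to 0.254 and 0.261. Lgals1, which encodes galectin-1, was at -0.77 ± 0.15, angiotensinogen, Agt, at -0.48 ± 0.09, the lysozyme gene Lyz1 at -0.45 ± 0.09 and the muscle LIM protein gene Csrp3 at 0.41 ± 0.08, and their calls were lost in 11, 12, 15 and 14 omissions. Pebp1 (-0.37 ± 0.07) and the collagen gene Col5a3 (-0.34 ± 0.07) complete the 16. Both fall outside the naming rule and were chosen after their values were seen, and their calls were lost in 8 and 14 omissions.

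By list, 8 of the 41 tested lists were lower on the high-fat diet and 0 were higher. Of 16 genes of xenobiotic metabolism 2 fell, Ephx1 and Gstt2, and 0 rose, with 7 lower when adjusted over the list alone (median -0.24, camera adjusted p = 1.76e-06; adjusted p = 0.148 with an estimated correlation). Of 10 growth hormone responsive and sex-biased genes 1 fell, Cyp3a41a, and 0 rose, with 3 lower when adjusted over the list alone (median -0.21, camera adjusted p = 1.76e-06; adjusted p = 0.136 with an estimated correlation). Of 9 acute phase genes 2 fell, Saa2 and Hp, and 0 rose, as when adjusted over the list alone (median -0.32, camera adjusted p = 0.000401; adjusted p = 0.136 with an estimated correlation). The other 5 lists had 0 members past the limma threshold over all genes. The medians were -0.12 for 20 ribosomal protein genes (7 lower and 1 higher at unadjusted p below 0.05, 1 lower adjusted over the list alone; camera adjusted p = 9.07e-06; adjusted p = 0.498 with an estimated correlation) and -0.13 for 9 genes of oxidative phosphorylation (4 lower at unadjusted p below 0.05, 2 adjusted over the list alone; camera adjusted p = 0.00112; adjusted p = 0.326 with an estimated correlation). Plasma protein genes had a median of -0.12 (3 of 11 lower at unadjusted p below 0.05, 0 adjusted over the list alone; camera adjusted p = 0.00189; adjusted p = 0.509 with an estimated correlation), Kupffer cell markers of -0.20 (4 of 12 and 0; camera adjusted p = 0.00438; adjusted p = 0.509 with an estimated correlation) and amino acid catabolism genes of -0.13 (3 of 13 and 0; camera adjusted p = 0.005; adjusted p = 0.51 with an estimated correlation).

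Several genes tied to dietary fat did not pass in high-fat livers. Cyp4a14 was at -0.55 ± 0.23 (adjusted p = 0.711), Acot1 at -0.48 ± 0.20 (adjusted p = 0.735), the fatty acid transporter Cd36 at -0.31 ± 0.17 (adjusted p = 0.939), the nuclear receptor gene Pparg at -0.20 ± 0.08 (adjusted p = 0.691), the lipid droplet protein Plin2 at 0.14 ± 0.08 (adjusted p = 0.997), Scd1 at -0.14 ± 0.22 (adjusted p = 0.997) and Fgf21 at 0.48 ± 0.15 (adjusted p = 0.342). Angptl4 (-0.39 ± 0.13, adjusted p = 0.397) and Pck1 (0.14 ± 0.15, adjusted p = 0.997) did not pass either.

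At unadjusted p below 0.05, 326 named genes differed between high-fat and control livers, and 24 unnamed spots passed after adjustment, each of them lower. The split was 10 higher and 20 lower with each array centred on its median, and 16 and 24 with arrays scaled to the same spread. The total of 16 was 6 with direct pairs alone, 186 with first arrays alone and 34 without the pair of fasted mouse 15 and control mouse 2, whose second array had the widest spread of all; leaving out single mice gave 7 without control 4, 9 without control 5, 8 without high-fat 7, 8 or 10, 5 without high-fat 9, 8 without fasted 11, 10 without fasted 12 or 14, 7 without fasted 13 and 31 without fasted 15.

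The third comparison set fasted directly against high-fat livers and also tests whether the responses to the fast and to the diet differed. Of the named genes 159 were higher in fasted livers and 147 were lower. Pkm rose by 4.11 ± 0.29, or 17.3-fold (adjusted p = 8.05e-08), with a mean of 3.87 ± 0.30 (SD, n = 5) over the direct pairs. Cyp4a14 rose by 3.93 ± 0.23 (15.3-fold, adjusted p = 1.05e-08) and Apoa4 by 2.74 ± 0.18 (6.67-fold, adjusted p = 2.64e-08). Cyp3a41a was 3.06 ± 0.19 higher in fasted than in high-fat livers (8.35-fold, adjusted p = 2.6e-08). It stood at -3.15 in high-fat against control livers and was not called in fasted against control livers. Fabp5 was the most reduced named gene, at -3.28 ± 0.29 (adjusted p = 1.19e-06). Each had the same sign in 5 of 5 direct pairs.

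Fatty acid oxidation genes were higher in fasted than in high-fat livers. The peroxisomal and microsomal list had 6 of 10 genes higher and 0 lower, with 7 higher when adjusted over the list alone (median 0.41, camera adjusted p = 5.84e-08; adjusted p = 0.148 with an estimated correlation), among them Hsd17b4 (0.65 ± 0.08) and Ech1 (0.64 ± 0.08). The mitochondrial list had 5 of 7 higher and 0 lower, as when adjusted over the list alone (median 0.34, camera adjusted p = 3.96e-05; adjusted p = 0.148 with an estimated correlation), among them Slc25a20 (0.54 ± 0.08). Other PPARalpha-regulated genes went both ways, 3 of 15 higher and 2 lower, against 8 and 2 when adjusted over the list alone (median 0.24, camera adjusted p = 0.012; adjusted p = 0.33 with an estimated correlation). Acot1 (1.91 ± 0.20) and Vnn1 (1.05 ± 0.10) were higher, and Fabp1 (-1.48 ± 0.18) and Fabp2 (-0.57 ± 0.11) were lower. Cd36 (0.53 ± 0.17, adjusted p = 0.0799) and Plin2 (-0.19 ± 0.08, adjusted p = 0.264) did not pass.

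Carbohydrate and amino acid genes also differed. The gluconeogenesis list had 3 of 10 genes higher and 0 lower, as when adjusted over the list alone (median 0.20, camera adjusted p = 0.00972; adjusted p = 0.305 with an estimated correlation), among them Slc37a4 (0.95 ± 0.14). The glycolysis list had 2 of 11 higher and 1 lower, against 4 and 2 when adjusted over the list alone (median 0.08, camera adjusted p = 0.0371; adjusted p = 0.305 with an estimated correlation), and besides Pkm its higher member was Aldoa (1.64 ± 0.11). Ldhb, outside the list, rose by 2.29 ± 0.12 (adjusted p = 6.24e-09). Of 13 genes of amino acid catabolism 6 were higher and 2 lower, against 7 and 3 when adjusted over the list alone (median 0.34, camera adjusted p = 0.0154; adjusted p = 0.48 with an estimated correlation), including Arg1 (1.29 ± 0.13) and Aass (1.34 ± 0.16). Bhmt rose by 1.55 ± 0.18 and Nsg2, a protein of neuronal vesicles, by 1.61 ± 0.09 (adjusted p = 6.24e-09).

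Fatty acid synthesis genes were lower in fasted livers, 5 of 10 against 0 higher and 6 when adjusted over the list alone (median -0.31, camera adjusted p = 0.0001; adjusted p = 0.148 with an estimated correlation). Elovl3 was at -1.40 ± 0.19, Mlxipl at -0.86 ± 0.10 and Acss2 at -0.85 ± 0.13. Of 7 cholesterol synthesis genes 4 were lower and 0 higher, with 5 lower when adjusted over the list alone (median -0.52, camera adjusted p = 2.52e-05; adjusted p = 0.148 with an estimated correlation), including Nsdhl (-1.24 ± 0.24) and Ebp (-0.53 ± 0.08). Cyp7a1 rose by 1.89 ± 0.34 (adjusted p = 0.00205) and Abcb11 was lower, at -1.62 ± 0.13 (adjusted p = 4.75e-07). Of 11 plasma protein genes 3 were lower and 0 higher, with 4 lower when adjusted over the list alone (camera adjusted p = 0.0113; adjusted p = 0.451 with an estimated correlation). Car3 (-2.01 ± 0.24), Camp (-2.32 ± 0.19) and Hsd3b1 (-2.12 ± 0.25) were lower too.

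Genes of xenobiotic metabolism went both ways in fasted against high-fat livers, 5 of 16 higher and 2 lower, against 9 and 3 when adjusted over the list alone (median 0.42, camera adjusted p = 0.00519; adjusted p = 0.322 with an estimated correlation). Gstt2 rose by 1.15 ± 0.10 (adjusted p = 1.44e-06) and the cytochrome P450 gene Cyp3a13 by 0.89 ± 0.12 (adjusted p = 0.000138). Haptoglobin, Hp, was higher by 0.99 ± 0.14 (adjusted p = 0.000335). Of 13 interferon response and antigen presentation genes 5 were lower and 0 higher, with 8 lower when adjusted over the list alone (median -0.37, camera adjusted p = 2.52e-05; adjusted p = 0.289 with an estimated correlation). Ifit3, an interferon-induced gene, was at -0.57 ± 0.13 (adjusted p = 0.0109), and its call was lost without high-fat mouse 9 (adjusted p = 0.0861), fasted mouse 11 (adjusted p = 0.0671) or fasted mouse 13 (adjusted p = 0.0527). Kupffer cell markers moved the same way as this list, with a median of -0.22 over 12 genes, of which 0 passed the limma threshold over all genes and 4 were lower when adjusted over the list alone (camera adjusted p = 0.0186; adjusted p = 0.451 with an estimated correlation).

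The proteasome list had 4 of 16 genes higher and 0 lower, with 7 higher when adjusted over the list alone (camera adjusted p = 0.000349; adjusted p = 0.323 with an estimated correlation), including Psmd4 (0.66 ± 0.09). The translation list had 2 of 12 higher and 0 lower, with 3 higher when adjusted over the list alone (camera adjusted p = 0.00691; adjusted p = 0.172 with an estimated correlation). Among them was Npm1 (0.39 ± 0.08, adjusted p = 0.00648), whose call was lost without high-fat mouse 10 (adjusted p = 0.059). Heat shock genes (3 of 10 higher, 4 adjusted over the list alone; camera adjusted p = 0.0154; adjusted p = 0.33 with an estimated correlation), periportal hepatocyte markers (3 of 9 higher, 4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00972; adjusted p = 0.289 with an estimated correlation) and pericentral ones (3 of 11 higher, the same adjusted over the list alone; camera adjusted p = 0.0455; adjusted p = 0.305 with an estimated correlation) were also higher. The ribosomal protein list passed with a median of 0.10 and 0 of 20 members past the limma threshold, over all genes or adjusted over the list alone (camera adjusted p = 0.0233; adjusted p = 0.614 with an estimated correlation).

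**Figure D3:**
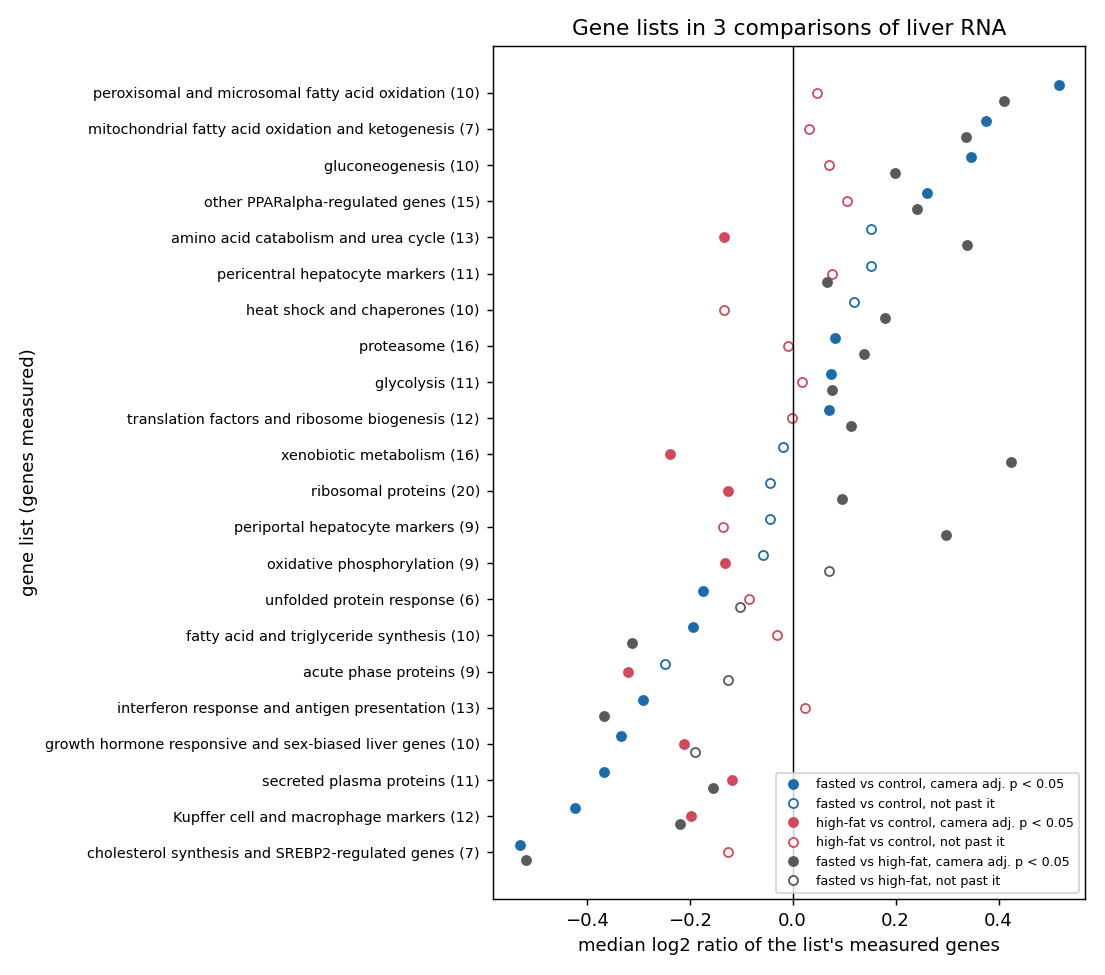
Median log2 ratio (horizontal axis) of the measured genes of each list (vertical axis, number measured in brackets) in the 3 comparisons. Filled circles passed camera at an adjusted p below 0.05 with the preset correlation and open circles did not; fatty acid oxidation lists lie to the right and cholesterol synthesis to the left where fasted livers are compared.

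At unadjusted p below 0.05, 888 named genes differed between fasted and high-fat livers, and 150 unnamed spots were higher and 169 lower after adjustment. The total of 306 named genes became 87 with the 5 direct pairs alone, 498 with first arrays alone, 90 with second arrays alone and 631 with pairs weighted by quality, and it was 199 without high-fat mouse 8, 176 without high-fat mouse 9, 184 without high-fat mouse 10, 175 without fasted mouse 11 and 197 without fasted mouse 13.

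The fast and the high-fat diet shared 10 calls of the same direction against control. Apoa4, Fabp2 and Csrp3 were higher in both, and Saa2, Lgals1, Car14, Lyz1, Madcam1, Col5a3 and Pebp1 were lower in both. Apoa4 stood at 4.62 in fasted and 1.88 in high-fat livers, Fabp2 at 0.81 and 1.38, and Lgals1 at -1.16 and -0.77. Madcam1 stood at -1.03 and -1.71, with its call in fasted livers lost in 11 of 15 omissions. Saa2 fell by 1.00 and 1.09, with its call in fasted livers lost without fasted mouse 11 (adjusted p = 0.0585). Its value in fasted livers ran from -1.20 to -0.58 over the omissions of a mouse. Gstt2 was the 1 gene called in opposite directions, at 0.63 in fasted and -0.51 in high-fat livers. Independent lists of these lengths would share 0.124 higher and 0.721 lower genes, and 20 simulations of unchanged groups measured against the same controls shared at most 0 calls. Groups without changes give hardly any calls, so that value sets no bound for lists of this length. Leaving out 1 mouse at a time gave 3 to 18 shared calls. Across all 4799 genes, which are not independent replicates, the log2 ratios correlated with Pearson's r = 0.375, whereas the simulations gave 0.53 from the shared controls alone. The covariance was 0.0143 against a simulated 0.00681, a difference of 0.00753. The same-sign share was 67.0% against a simulated 67.5%. With the control mice split in 6 ways into separate groups for each comparison and direct pairs only, shared calls numbered 0 to 7 with a mean of 2, and r ranged from -0.0782 to 0.261. The fasted side of each split then rested on 2 pairs and called 0 to 117 genes. Splits with control 2 on that side called at most 1 gene there, so hardly any could be shared. The lower number of shared calls therefore decides nothing on the shared controls.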

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

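The tests of muscle genes, of Kupffer cell against other cell markers, of male-biased genes and of list members in each dye orientation were chosen after the results they bear on were seen; the tests of low oxygen, Y-linked genes, the signs of called genes and regrouped mice were written down before their results were seen.

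The genes Pkm, Ldhb, Aldoa, Ldha and Bnip3, chosen after their values were seen, were higher in fasted livers, with a median log2 ratio of 1.40 and a smallest of 0.57; other glycolytic genes such as Hk1 (-0.23), Hk2 (-0.04), Pfkp (-0.03), Pgk1 (0.11) and Tpi1 (0.20) did not pass. A response to low oxygen would raise other hypoxia-inducible genes, but 21 of them had a median of -0.044 (95% bootstrap interval -0.11 to 0.09), and the 2 whose spots are seen to respond, Ndrg1 (-0.92) and P4ha2 (-0.34), fell, with their calls lost in 0 and 13 of 15 omissions of a mouse. Ndrg1 and P4ha2 thus moved against a response to low oxygen. The signal of the other hypoxia-inducible genes is unknown, so low oxygen is not excluded. RNA from skeletal muscle stays open: 0 of 9 fixed markers passed and the median of 13 muscle genes was 0.081 (95% interval -0.04 to 0.24), but spots of unknown signal exclude nothing, and of the 4 genes that respond Tcap (0.86), Csrp3 (0.62) and Chrna1 (0.35) rose and Pygm (-0.46) fell (calls lost in 0, 0, 4 and 5 omissions). A response of hepatocytes to the fast stays open too and was not tested.

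Kupffer cell markers had a median of -0.42 over 12 genes in fasted against control livers. A larger share of hepatocyte RNA would lower the markers of every other cell type alike, and 49 markers of endothelial, stellate, bile duct, lymphoid, erythroid and neutrophil cells had a median of -0.06. The difference of -0.36 had a permutation p of 0.00016, but genes are not independent replicates. The Kupffer cell list was also taken up because it fell, and dim spots may read near 0. Of the 6 other markers whose spots are seen to respond, Hba-a1, Fech, Kdr, Tek and Camp fell and Dcn rose (0.29, call lost in 13 of 15 omissions). A larger share of hepatocyte RNA, fewer Kupffer cells and lower expression per cell therefore cannot be told apart.

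The xenobiotic and acute phase lists passed camera as lower on the high-fat diet, but only 2 of 16 and 2 of 9 members passed, those 4 calls were each lost in 5 to 12 of 15 omissions of a mouse, and the lists had adjusted p = 0.148 and 0.136 with an estimated correlation. The Y-linked genes Eif2s3y (-0.11 ± 0.06, adjusted p = 0.972) and Uty (-0.03 ± 0.12, adjusted p = 0.997) decide nothing on mice of the other sex in 1 group. Their signal is unknown, and dim spots may read near 0. The largest absolute ratio of these genes in any pair was 0.77, and 0.25 among high-fat and control pairs. Groups of different sex would raise male-biased genes where the female-biased Cyp3a41a fell, but 6 of them had a median of -0.13 (95% bootstrap interval -0.51 to 0.07), and 3, Elovl3, C6 and Gstp1, passed in fasted livers, so their spots respond; this argues against that cause, while single mice of the other sex stay open. The same sign of 16 of 16 called genes in the first and second arrays decides nothing on an effect of 1 dye orientation, because those genes were called on the mean of both, in which a dye bias common to all arrays cancels. A shift confined to the second arrays would not cancel and cannot be told apart from an effect of the diet, since the 25 list members had a median of -0.106 (95% bootstrap interval -0.40 to 0.13) over all named genes in the first arrays and -0.27 (-0.61 to -0.13) in the second.

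Whether other groupings of the same mice call as many genes was examined by exchanging group labels, with 100 of the 126 distinct splits drawn per comparison. For fasted against control, 1 of 100 splits, the real one, gave as many genes, with 465 against at most 363 in the others. For high-fat against control it was 1 of 100, with 16 against at most 2, and for fasted against high-fat 1 of 100, with 306 against at most 96. These shares do not measure chance, because the splits are not alike. Other splits can put directly hybridised mice in 1 group, and the real group differences then add to their spread. Of the 100 splits, 93, 92 and 92 gave 0 genes in the 3 comparisons.

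Single pairs or arrays stood far from the others of their group in 12 of 148 groups examined (8.11%), where chance gives about 1 in 20. The groups pool single genes with whole arrays, and those of the genes share the same pairs. They are therefore not independent, and the share does not show an excess among genes. In fasted against control pairs, Khk was -0.24 in the pair of fasted 14 and control 3, against -0.83 to -0.74 in the others. Pcx was 0.44 in the pair of fasted 13 and control 5, against 0.69 to 0.73, and Pygm was -1.13 in the pair of fasted 15 and control 2, against -0.41 to -0.33. In high-fat against control pairs, Saa2 was -2.18 in the pair of high-fat 9 and control 2, against -0.81 to -0.56. Plin2 was 0.20 in the pair of high-fat 8 and control 4, against 0.07 to 0.09. In the pair of high-fat 6 and control 1, Pck1 was 1.00, against -0.08 to 0.10, and Angptl4 was 0.24, against -0.63 to -0.40. In fasted against high-fat pairs, Bhmt was 0.56 in the pair of fasted 12 and high-fat 6, against 1.50 to 1.74, and Cyp3a13 was 1.81 in the pair of fasted 15 and high-fat 10, against 0.49 to 0.74.

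Among whole arrays, the second array of fasted 11 and high-fat 9 had a median log2 ratio of 0.35, against -0.05 to 0.13 for the other arrays of that comparison. The second array of fasted 15 and control 2 had a median of -0.23, against 0.03 to 0.19, and a standard deviation of 1.26, against 0.49 to 0.84.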

How the results depend on the processing

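The quality weights, the omission of the pair of fasted 15 and control 2, adjustment over named genes and averaging of adjacent unnamed spots were chosen after seeing the data. Counts are given as fasted against control, high-fat against control and fasted against high-fat, which were 465, 16 and 306. With the share of variance between mice set to 0.9 they were 79, 2 and 61, with direct pairs only 57, 6 and 87, with first arrays only 1559, 186 and 498, and at an adjusted p below 0.01 257, 6 and 173. A stricter threshold lowers counts by construction, and single arrays leave the dye bias in. Direct pairs only leave fewer pairs, which need not lower a count. High-fat against control rose to 34 when the pair of fasted 15 and control 2 was left out. For direct pairs and the other settings the cause was not tested. High-fat against control alone moved to 30 with centred arrays, 40 with scaled arrays, 32 with no replicate block for the mouse, 7 with a share of 0.5, 9 with both spots of a gene required, 34 without the pair of fasted 15 and control 2 and 31 with adjacent unnamed spots averaged. It was 33 with second arrays only and 40 with quality weights, where fasted against high-fat was 90 and 631. Without the genes of lower spread, fasted against control and against high-fat were 264 and 203, and with a log2 ratio of at least 0.5 also required 210 and 157. The robust prior, adjustment over named genes and omission of the separate chain kept every count within 1.5 times.

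Leaving out 1 mouse at a time gave 245 to 486, 5 to 31 and 175 to 368 genes, 3 to 18 shared calls, and 11 to 15, 8 to 12 and 13 to 18 list calls. Shared calls, 10 in all, were 17 with centred arrays, 3 at 0.01, 18 without the pair of fasted 15 and control 2 and 21 with quality weights. With split controls, which leave fewer pairs and fewer calls, their mean was 2. List calls, 14, 8 and 18, were 0, 0 and 0 with an estimated correlation, and 11 in fasted against high-fat with direct pairs. With first arrays only, Ttr (0.64) and Angptl4 (0.46) in fasted against control reversed, as did Dcn (-0.055) and Chrna1 (-0.00603) with second arrays only. Of the called genes named here, 60 of 74, 5 of 16 and 33 of 35 passed in every omission of a mouse, 28, 5 and 30 with direct pairs only and 35, 2 and 26 with a share of 0.9. Of 6 genes not called in fasted against control, 4 passed and 1 reversed with first arrays only. Requiring all 14 pairs or dropping the filter changed nothing to fit, since no cell was empty, so neither has a value. No paired analysis was possible by replicate number because the numbers in the titles name single mice; the unit of every fit is the hybridised pair, and the mouse is the block. Signal over background is unknown, so dim spots could not be set apart.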

Other observations

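Detoxification genes moved both ways in fasted livers, with 5 of 16 higher and 5 lower than in controls, the same numbers as adjusted over the list alone (camera adjusted p = 0.876). The glutathione transferases Gstm6 (-1.19 ± 0.15, adjusted p = 6.41e-05) and Gstp1 (-0.92 ± 0.14, adjusted p = 0.000389) were lower, whereas Gstt2 (0.63 ± 0.11, adjusted p = 0.000969) and Nr1i3, the gene of the xenobiotic receptor CAR (0.75 ± 0.11, adjusted p = 0.00041), were higher. Of 9 acute phase genes 4 were lower and 1 was higher, against 5 and 1 when adjusted over the list alone (camera adjusted p = 0.145). The lipopolysaccharide-binding protein Lbp was higher, at 0.56 ± 0.11 (adjusted p = 0.00301).

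Of 14 autophagy and lysosome genes 2 rose, Bnip3 (1.40 ± 0.11, adjusted p = 4.18e-07) and the protease Ctsl (0.77 ± 0.13, adjusted p = 0.000876), and 2 fell, against 3 and 3 when adjusted over the list alone (camera adjusted p = 0.876). Among 17 genes responsive to insulin, FOXO1 or glucocorticoids 3 rose and 1 fell, against 4 and 1 when adjusted over the list alone (camera adjusted p = 0.291). The member that fell was Igfals, which stabilises circulating IGF1 (-0.75 ± 0.11, adjusted p = 0.000367). The chemokine gene Cxcl9, of the interferon list, was at -0.87 ± 0.21 (adjusted p = 0.0129), and its call was lost without control 4 (adjusted p = 0.0988), control 5 (adjusted p = 0.0645), fasted 11 (adjusted p = 0.0998) or fasted 13 (adjusted p = 0.0741).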
